A study of Homo sapiens with 14 samples.

How the data were processed

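Guide amplicons were sequenced in 14 samples, 12 from HUDEP2 cells and 2 from plasmid libraries. Per the labels, the authors amplified guides from genomic DNA in a single PCR step with staggered barcoded primers. The deposited values are raw counts of reads per guide, with no normalisation. The submitters' processing notes name MAGeCK without a version and without its role, and the rule for matching reads to guides is not given in the sources used here. The genome-scale plasmid column had 41 blank cells and no 0, and these cells were set to 0. The secondary library came with guide sequences of 20 bases, and all 12444 were different. Guides that fit more than 1 gene were not looked for in the genome-scale library, whose sequences were not used here.

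Day and replicate number were taken from the labels, which do not state that replicates were separate cultures. The p-values of the gene and guide tests therefore measure the spread between these samples. The numbers were checked for pairing. In the genome-scale screen the deviations of day 0 and day 12 libraries from their group means correlated at 0.42, 0.37 and 0.36 for the same number and at -0.14 or less for different numbers. These correlations in the secondary screen were 0.63, 0.67 and 0.65, against -0.27 or less. The numbers were therefore taken to pair the samples, and fits with the replicate number as a block were run as alternatives. The main fits leave the block out, so their standard errors and p-values also hold the spread between pairs. The pairing comes from the shared numbers in the labels.

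Counts of all guides of a gene were summed per library, and genes with a mean sum of at least 30 over the 6 cell libraries were tested, 20653 in the genome-scale and 1223 in the secondary screen. Day 12 was compared with day 0 by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Libraries were scaled by TMM in the genome-scale screen and by the total of the non-targeting guides in the secondary screen. A gene counted as lower or higher at a Benjamini-Hochberg adjusted p under 0.05 when its median guide had the same sign. Guides with a mean count of at least 10 were tested in the same way. Non-targeting guides were put in 166 sets of 6 and 50 sets of 10 and tested like genes. Log2 fold changes are given with the standard error of the fit.

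A set of 37 gene lists was fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists with at least 3 tested members were tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a screen. Camera with an estimated correlation and fry were run beside it. Camera compares the members of a list with all other genes, so its p-values do not rest on the spread between samples alone. For heme synthesis the estimated correlation was -0.053 in the genome-scale and -0.052 in the secondary screen, below the preset 0.01. The higher adjusted p with an estimated correlation therefore does not come from correlated members in that list. The genes named were, in each screen, the 10 largest rises and 10 largest falls among called genes with at least 3 guides, of which 2 of 3 or more had the sign of the gene, and with 1 sign in all 9 pairs of libraries. Also named were up to 4 members of each list with the smallest p, a fixed set of erythroid and cell cycle regulators, and the 10 genes called in both screens, ranked by the smaller of their absolute changes. The last were taken from the block calls of the genome-scale screen, since its calls without the block numbered 0. Genes called with the block, ENY2, SPTSSA and the genes under the other observations were chosen after their values were seen. Some genes that the rule names are not reported here. Symbols are those of the deposited tables, and current names were taken from the RefSeq gene table. It matched 17344 of 20663 genome-scale names as current and 1347 as older symbols, 1795 were microRNA entries and 177 had no match. The secondary library had 1037 current names, 96 older, 82 microRNA entries and 8 without a match.

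Day 0 was set against plasmid as the log2 ratio of CPM, with the mean of the 3 day 0 libraries and a pseudocount of 0.5. The median of a list was placed among 10000 random lists of the same size and like plasmid counts. Evenness was measured by the Gini index and compared by an exact permutation test over 20 arrangements. Screens were compared by Fisher's exact test and by correlation across genes.

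Alternatives were total count, RLE, TMM and non-targeting scaling, other count minimums, DESeq2 1.42.0, limma-trend on mean log2 guide counts, a guide-level test combined by alpha-RRA, sums without the most abundant guide, no condition on the median guide, the replicate block and the loss of each library in turn. The alpha-RRA was written anew, with an alpha of 0.25, and is not MAGeCK. Fits without the libraries numbered 3 and further scalings for lists were added after the data were seen.

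The methods were tested on simulated counts with the depth and spread of each screen. Of 200 changed genes in each design, the gene test recovered 1 of 66, 38 of 62 and 70 of 72 with true changes of 0.5, 1 and 2 log2 in the genome-scale design, and 63 of 66, 66 of 66 and 68 of 68 in the secondary design, with 5 false calls in each. A list made only of genes lowered by 0.5, 1 or 2 log2 was found and 0 of 37 random lists were called. Most lists called in the genome-scale screen had smaller median shifts, whose detection was not measured. Spread was drawn for each gene on its own, so members of the simulated lists were not correlated. The real complex I list had an estimated correlation of 0.28 in the genome-scale screen. The simulation therefore cannot tell how often correlated lists are called falsely. Alpha-RRA treats the guides of a gene as independent. When the simulated spread was drawn for each guide on its own, it made 5 false calls in the genome-scale and 0 in the secondary design. When the spread was shared by the guides of a gene it made 4406 and 318. On the real genome-scale counts it called 35 genes lower and 14 higher, far below 4406, which argues against fully shared spread in that screen. A partly shared spread was not tested. PCR reads without molecular identifiers are not independent molecules, so depth covers counting error only.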

Results

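Pooled CRISPR knockout screens were run in HUDEP2 cells, an immortalised human line of erythroid precursors, and the guides in the cells were counted by sequencing. The series title names the modulators of erythropoiesis as the subject. The genome-scale library was GeCKO v2, with 119461 guides against 20663 genes and 1000 non-targeting guides among them. The secondary library held 12444 guides against 1223 genes, with 500 non-targeting guides among them and 10 guides for each of 1173 genes. Each screen had 3 replicates at day 0, 3 replicates at day 12 and 1 plasmid library, which makes 14 samples. Whether the cells were expanded or differentiated between the days is not given in the sources used here.

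Sequencing depth in the genome-scale screen was 22364167 counts for the plasmid library. The day 0 libraries held 21270296, 27885515 and 15208638 counts in replicates 1, 2 and 3, and the day 12 libraries 22430895, 21260144 and 15654215. The plasmid library of the secondary screen held 11952916 counts, its day 0 libraries 34112156, 30361288 and 32920512 and its day 12 libraries 28049320, 27351536 and 30620810. The median guide had 98 to 193 counts in the cell libraries of the genome-scale screen and 1842 to 2512 in those of the secondary screen. Non-targeting guides took 4.02% of the reads in genome-scale day 0 replicate 3, against 1.68% and 1.66% in day 0 replicates 1 and 2 and 1.70% to 1.77% at day 12. Their share in the secondary screen was 5.12% to 5.19% at day 0 and 5.71% to 5.83% at day 12. The plasmid libraries had 0.740% and 3.65%.

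**Figure D1:**
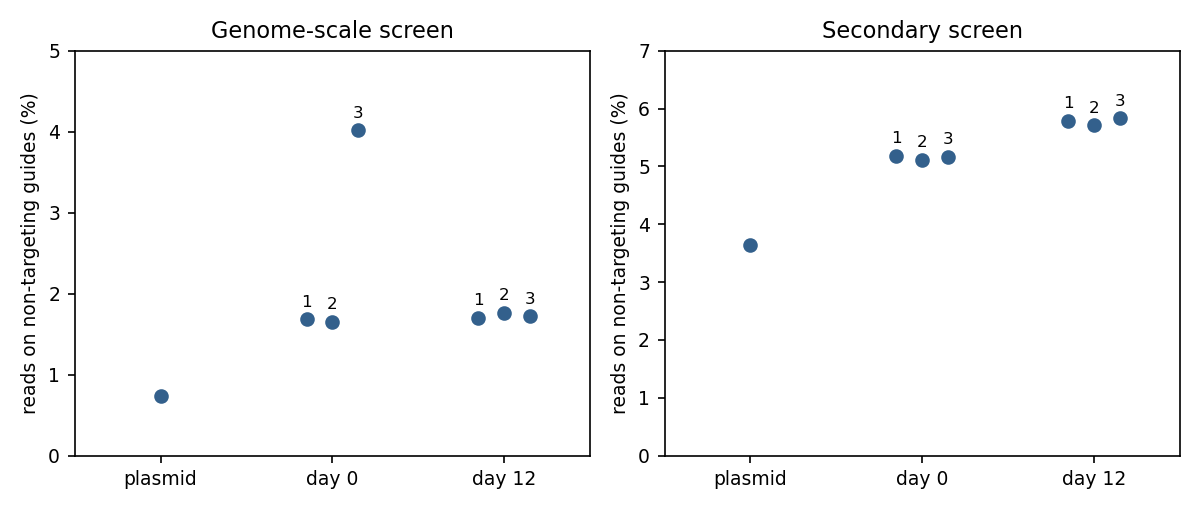
Share of reads on non-targeting guides (percent, vertical axis) in each plasmid, day 0 and day 12 library of the genome-scale screen (left) and the secondary screen (right). Each point is 1 library and the number above it is its replicate; genome-scale day 0 replicate 3 stands at 4.02%, and the other genome-scale cell libraries lie between 1.66% and 1.77%.

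The comparison of day 12 with day 0 asks which knockouts made cells scarcer or more common over the interval. In the genome-scale screen the guides against heme synthesis fell as a group. The 17 genes of this list had a median log2 fold change of -0.56, and 14 of them were below 0 (camera, adjusted p = 2.60e-11; adjusted p = 0.0564 with an estimated correlation). The values were -1.31 ± 0.16 (log2 fold change ± SE, 3 replicates per day) for ALAS2, the erythroid enzyme that starts heme synthesis and -0.73 ± 0.16 for PPOX, a later enzyme of the pathway. No member passed edgeR's test over all genes, 8 were lower when adjusted over the list alone, and ALAS2 and UROD, another enzyme of the pathway, were among those lower over all genes with the replicate number as a block.

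Respiratory chain complex I, the entry point of electrons from NADH, fell as well. Its 46 genes had a median of -0.49 (camera, adjusted p = 8.79e-18; adjusted p = 0.0740 with an estimated correlation), and 8 were lower when adjusted over the list alone against 0 over all genes. Values were -1.49 ± 0.27 for NDUFS6, a subunit and the single member called with the block, -1.16 ± 0.29 for the assembly factor NDUFAF3 and -0.78 ± 0.22 for the subunit NDUFB9. The median was -0.82 in the pair of libraries numbered 3, against -0.25 and -0.26 in the pairs numbered 1 and 2. Without day 0 replicate 3, the library with the non-targeting excess, the list fell by a median of -0.20 (adjusted p = 7.60e-09).

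The machinery of protein synthesis and turnover also fell. The medians were -0.25 for 77 cytosolic ribosomal proteins (camera, adjusted p = 1.30e-10), -0.21 for 75 mitochondrial ribosomal proteins (adjusted p = 1.29e-08) and -0.26 for 32 proteasome genes (adjusted p = 7.60e-08, with a median of -0.40 without day 12 replicate 1). With an estimated correlation the adjusted p was 0.0564 for each of these lists. RPL23, of the large ribosomal subunit, had a value of -1.09 ± 0.26, MRP63 (now MRPL57), of the mitochondrial ribosome, -1.06 ± 0.28, and PSMB5, a catalytic subunit of the proteasome, -1.74 ± 0.37. PSMB5 was lower when adjusted over the list alone, as were GLRX5 of iron-sulfur cluster assembly (-0.99 ± 0.21), the Mediator subunit MED23 (-0.88 ± 0.21), the glutathione enzyme GCLC (-0.94 ± 0.21), the ATP synthase assembly factor ATPAF2 (-0.96 ± 0.18) and the initiation factor subunit EIF3H (-0.80 ± 0.18). Each was the single such member of its list, and over all genes edgeR called none of them; GLRX5 was called with the block.

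Erythropoietin and KIT signalling, which carries growth signals into erythroid precursors, fell with a median of -0.25 over 36 genes (camera, adjusted p = 3.88e-05; 0.0602 as the adjusted p with an estimated correlation). EPOR, the erythropoietin receptor, had -1.78 ± 0.50 and AKT1, a kinase downstream of it, -0.63 ± 0.20, and no member passed the test over all genes or over the list alone. This list depended on the libraries numbered 3, with a median of -0.07 (adjusted p = 0.0167) without day 0 replicate 3 and -0.04 (adjusted p = 0.0596) without both. The erythroid transcription factors and cofactors fell by a median of -0.14 over 39 genes (adjusted p = 0.000799; adjusted p = 0.0929 with an estimated correlation). Within them ZBTB7A, a repressor of the fetal globin genes, had +1.02 ± 0.21 and was higher when adjusted over the list alone and with the block. GATA1, the main erythroid transcription factor, had -0.14 ± 0.25, KLF1, an activator of adult globin, -1.08 ± 0.52, TAL1 -0.32 ± 0.18, LMO2 -0.43 ± 0.21 and MYB -0.20 ± 0.22. The other fixed regulators, JAK2, KIT, STAT5A, STAT5B, LDB1, BCL11A, TFRC, BCL2L1, MCL1, CDKN1B, RB1, SH2B3, VHL, RASA3, BAX, MYC, CCND3 and CDK6, lay between -0.79 ± 0.31 for STAT5A and +0.44 ± 0.19 for KIT, and none passed.

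Other lists that fell were respiratory chain complexes III to V, the spliceosome, cholesterol synthesis, the mitotic spindle and kinetochore, DNA replication, RNA polymerases, Mediator, iron uptake and iron-sulfur assembly, translation factors, mTORC1 and amino acid sensing, the Diamond-Blackfan and congenital dyserythropoietic anaemia genes, red cell glycolysis and redox enzymes, G1/S cyclins and kinases, Polycomb repressive complex 2 with NuRD, and the list of tumour suppressors and cell cycle inhibitors, called the tumour suppressors for short. Their medians lay between -0.25 and -0.05, the adjusted p by camera between 3.50e-06 and 0.0469, and the adjusted p with an estimated correlation between 0.0564 and 0.328. The call of G1/S cyclins and kinases was lost without day 0 replicate 3 (adjusted p = 0.790) and without day 12 replicate 1 (0.0603), 2 (0.229) or 3 (0.152). That of the tumour suppressors was lost without day 0 replicate 3 (adjusted p = 0.129, median +0.01) and without day 12 replicate 1 (0.114), 2 (0.0505) or 3 (0.198). Polycomb repressive complex 2 with NuRD lost its call without day 0 replicate 3 (0.240) and without day 12 replicate 1 (0.225) or 2 (0.188). Without day 12 replicate 1, mTORC1 and amino acid sensing (0.197) and red cell glycolysis and redox enzymes (0.0571) also lost theirs. Without both libraries numbered 3 the calls of G1/S cyclins and kinases (0.984) and of the tumour suppressors (0.301) were lost as well. Medians also moved by over 1.5 times when 1 library was left out. Without day 0 replicate 1 the Diamond-Blackfan genes had -0.16. Without day 0 replicate 2 Polycomb repressive complex 2 with NuRD had -0.16 and the tumour suppressors -0.17, and without day 0 replicate 3 the G1/S list had -0.01. Without day 12 replicate 1 the G1/S list had -0.20, the tumour suppressors -0.16, mTORC1 and amino acid sensing -0.11 and Polycomb with NuRD -0.10. Without day 12 replicate 2 the RNA polymerases had -0.10, DNA replication -0.25, translation factors -0.20 and the tumour suppressors -0.15, and without day 12 replicate 3 Polycomb with NuRD had -0.16 and glycolysis and redox enzymes -0.18. Scaling to the non-targeting guides moved the median of all genes from 0.02 to 0.26, and the medians of the lists that fell then turned positive except for heme synthesis (-0.33), complex I (-0.16), the proteasome, the spliceosome, cytosolic ribosomal proteins and congenital dyserythropoietic anaemia genes. This scaling carries the non-targeting excess of day 0 replicate 3, where these guides took 4.02% of reads against 1.66% to 1.77% in the other cell libraries, so the change of sign says nothing about the lists. All lists that fell were still lower than the other genes by camera, and the survival genes were then lower too (adjusted p = 0.0406).

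Higher lists in the genome-scale screen were negative regulators of growth signalling, globin genes and olfactory receptors. The 35 negative regulators rose by a median of 0.11 (camera, adjusted p = 0.00145; adjusted p = 0.0564 with an estimated correlation), with +0.47 ± 0.14 for the growth inhibitor NF1 and +0.51 ± 0.18 for CISH, an inhibitor of cytokine receptors. The 10 globin genes were split, with 5 below 0 and a median of 0.09, and camera placed the list above the other genes (adjusted p = 0.0286; adjusted p = 0.106 with an estimated correlation). Over the list alone 3 were higher, against 0 over all genes and 0 with the block. These were HBA1, an alpha-globin gene (+0.65 ± 0.18), HBB, the adult beta-globin gene (+0.46 ± 0.14), and AHSP, the chaperone of free alpha-globin (+0.79 ± 0.24). The globin call was lost without day 12 replicate 1 (adjusted p = 0.167, median 0.14), AHSP had +0.52 without day 12 replicate 3, and the median was 0.02 without day 12 replicate 2. The 371 olfactory receptors, which blood cells are not known to need, rose by a median of 0.07 (adjusted p = 0.0281; adjusted p = 0.0564 with an estimated correlation), a call lost without day 0 replicate 3 (0.0625) and without day 12 replicate 1 (0.152, median 0.05) or 2 (0.0830).

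Lists that did not pass were apoptosis effectors, autophagy, tRNA synthetases, Fanconi anaemia genes, genes of other blood lineages, hypoxia response, keratins, microRNA genes, red cell membrane genes, SAGA and the survival genes. Their medians lay between -0.20 and 0.06 and the adjusted p between 0.0772 and 0.998. The median of SAGA was 0.03, and its call appeared without day 0 replicate 3 (adjusted p = 0.0228) or day 12 replicate 2 (0.0196). The survival genes, with a median of -0.20, were lower with the block (adjusted p = 0.0286), without day 0 replicate 1 (0.0182) or 2 (0.0215) and without day 12 replicate 3 (0.0347). They were not called without day 0 replicate 3 (median -0.09, adjusted p = 0.524) or without day 12 replicate 1 (-0.12, 0.595) or 2 (-0.16, 0.154), so the median of this list depended on single libraries. The microRNA genes were called without day 0 replicate 1 (0.0401) and the tRNA synthetases without day 12 replicate 3 (0.0448) and without both libraries numbered 3 (0.0311). For autophagy the median was 0.05 and the mean -0.01, and for genes of other blood lineages the median was -0.03 and the mean 0.01, with camera's direction down for both. When 1 library was left out the medians of these 2 lists, the apoptosis effectors, hypoxia response, keratins, red cell membrane genes and SAGA changed sign. In total camera called 23 lists lower and 3 higher out of 37, fry called 14, and 0 passed with an estimated correlation.

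At the level of single genes edgeR without the replicate block called 0 of 20653 in the genome-scale screen, with 551 lower and 398 higher at an unadjusted p under 0.05. This fit leaves out the pairing of the libraries by number. DESeq2 called 45 lower and 11 higher, limma-trend 3 lower, and the guide-level test with alpha-RRA 35 lower and 14 higher. With the replicate number as a block edgeR called 21 lower and 8 higher, and these genes were named after their values were seen. Beside the heme enzymes they included SRM (-1.30 ± 0.32), which makes spermidine, the stress kinase MAPK14 (-1.14 ± 0.37), and on the other side the sphingomyelin synthase SGMS1 (+1.25 ± 0.20), the ceramide carrier COL4A3BP (now CERT1; +1.04 ± 0.15), the endosomal GTPase RAB7A (+0.98 ± 0.16) and CCZ1 (+1.02 ± 0.15), part of the exchange factor of RAB7A. Without day 0 replicate 3 edgeR called SGMS1 alone. Day 12 and day 0 differed in the same direction in all 9 pairs of libraries for 11.3% of genes, against 10% by chance if the libraries were exchangeable, a share that leaves out their pairing by number. Single guides gave 0 calls among 117560 tested, with 3348 at an unadjusted p under 0.05. With the block 14 were lower and 3 higher, and DESeq2 called 53 and 8. Of the 166 sets of non-targeting guides 0 passed and 12 had an unadjusted p under 0.05, and their median was -0.51 with the excess in day 0 replicate 3.

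Day 0 was compared with the plasmid library to ask which guides were already scarce at the start of the interval. With 1 plasmid library there was no test. In the genome-scale screen the median log2 ratio was -0.72 for cytosolic ribosomal proteins, -0.61 for the spliceosome, -0.55 for RNA polymerases, -0.54 for the proteasome and -0.53 for DNA replication. Each was below all of 10000 random lists of the same size and like plasmid counts. Heme synthesis had -0.18, at percentile 5 of the random lists, and complex I -0.06, at percentile 19.1. The day 0 mean includes replicate 3, where complex I had a median log2 of 0.60 against replicates 1 and 2. That library raises the ratio of complex I, so its ratio here does not show whether these guides were already scarce. For single regulators the ratio was -2.63 for EPOR, -2.05 for JAK2, the kinase bound to it, -1.84 for KLF1, -1.78 for MYC and -1.18 for GATA1. Of the 37 lists 19 were below the 2.5th percentile, and the apoptosis effectors (0.12) and the microRNA genes (0.14) were above the opposite limit. The non-targeting guides themselves had a median ratio of 1.65, so all of these ratios are relative to the other guides of the same library. The value of 1.65 is raised by day 0 replicate 3, where these guides took 4.02% of reads, against 1.68% and 1.66% in replicates 1 and 2.

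Guide counts became less even over the interval. In the genome-scale screen the Gini index was 0.342 in the plasmid library, 0.410 ± 0.018 (SD, n = 3) at day 0 and 0.466 ± 0.0098 at day 12, with 0.403% and 1.84% of guides at 0 counts. The secondary screen had 0.228, 0.326 ± 0.00077 and 0.418 ± 0.0029, with 0.177% and 0.388% of guides at 0. Every day 12 library lay above every day 0 library in both screens, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows.

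The secondary screen repeated the comparison of day 12 with day 0 on chosen genes, scaled to the non-targeting guides. Heme synthesis genes were among the largest falls. ALAS2 fell by 1.89 ± 0.083 (log2 fold change ± SE, 3 replicates per day; adjusted p = 1.64e-07), to 0.269 of its day 0 level, and ALAD by 1.67 ± 0.091, and PPOX had -1.64 ± 0.14. The other large falls were SLC25A1, the mitochondrial citrate carrier (-1.95 ± 0.13), the glycolytic enzyme TPI1 (-1.91 ± 0.12), SLC4A1, the anion exchanger of the red cell membrane (-1.48 ± 0.10), GLRX5 (-1.47 ± 0.14), the lysosomal amino acid transporter SLC36A1 (-1.37 ± 0.090) and hsa-mir-3929, a microRNA with 4 guides (-1.62 ± 0.42). Apart from hsa-mir-3929 (adjusted p = 0.00784), edgeR gave adjusted p values of 1.43e-05 or less for these genes, and each was lower in 9 of 9 pairs of libraries.

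The rises were led by COL4A3BP (CERT1), which carries ceramide from the endoplasmic reticulum to the Golgi. Its guides rose by 1.71 ± 0.11 (adjusted p = 1.43e-06), to 3.28 times the day 0 level. HBA1 rose by 1.48 ± 0.075, with guides that were not told apart here from those of its near-identical copy HBA2, and BBC3, which encodes the apoptosis inducer PUMA, by 1.12 ± 0.077. C18orf8 (now RMC1) and CCZ1, both of the exchange factor that activates RAB7A, rose by 1.09 ± 0.071 and 1.01 ± 0.086, and CCZ1 also has a near-identical copy, CCZ1B. PI4KB, a Golgi lipid kinase, rose by 1.02 ± 0.090 and C10orf76 (now ARMH3), which binds it, by 0.78 ± 0.092. SGMS1, which turns ceramide into sphingomyelin, rose by 0.88 ± 0.11, NF1 by 0.87 ± 0.072 and WDR91, a protein of endosomes, by 0.77 ± 0.071. All had an adjusted p of 6.26e-05 or less by edgeR and were higher in 9 of 9 pairs of libraries.

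Of the fixed lists, 8 of 8 heme synthesis genes fell, with a median of -1.48 (camera, adjusted p = 1.48e-05; adjusted p = 0.181 with an estimated correlation), UROS among them by 1.33 ± 0.084. Iron uptake and iron-sulfur assembly fell in 7 of 7 genes, with a median of -0.69 (adjusted p = 0.0170; adjusted p = 0.264 with an estimated correlation), among them the iron transporter SLC11A2 (-0.89 ± 0.11) and the assembly factor IBA57 (-0.77 ± 0.095). Cytosolic ribosomal proteins fell in 20 of 24 genes (median -0.55, adjusted p = 0.0115; adjusted p = 0.264 with an estimated correlation), with RPL39 at -0.75 ± 0.10 and RPLP1 at -0.67 ± 0.11. Complex I fell in 15 of 17 genes, or 16 when adjusted over the list alone (median -0.45, adjusted p = 0.0115; adjusted p = 0.326 with an estimated correlation), with NDUFAF3 at -0.89 ± 0.096 and NDUFA2 at -0.78 ± 0.11. Mitochondrial ribosomal proteins fell in 10 of 11 genes, or 11 over the list alone (median -0.47, adjusted p = 0.0339; adjusted p = 0.332 with an estimated correlation), led by MRP63 (-0.93 ± 0.14) and MRPL36 (-0.88 ± 0.099). That call was lost without day 0 replicate 2 (adjusted p = 0.0513) or day 12 replicate 3 (0.0667).

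SAGA, a chromatin complex that acetylates histones at promoters, was the list that rose. The adjusted p was 0.000255 by camera and the adjusted p with an estimated correlation was 0.332, and the median was 0.44. SUPT7L (+0.74 ± 0.12), SUPT20H (+0.63 ± 0.095), TADA1 (+0.44 ± 0.087) and TADA2B (+0.31 ± 0.082), all structural or adaptor subunits, were the 4 of 5 members that rose, and the fifth, ENY2, had -0.29 ± 0.12 and did not pass over all genes. ENY2 was called lower when adjusted over the list alone, with the block (-0.31), DESeq2 (-0.29) and limma-trend (-0.50), without the most abundant guide (-0.43) and without day 12 replicate 1 (-0.45). These lists hold genes that the study had chosen for the secondary library, so their directions are not independent evidence. The calls of SAGA and of the lists that fell held under TMM, RLE and total count scaling, where RLE moved the medians to -0.34 for cytosolic ribosomal proteins, -0.27 for mitochondrial ribosomal proteins and -0.25 for complex I. Counts adjusted over the list alone are given for the lists where they differ from those over all genes.

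Most members of the growth signalling and erythroid factor lists fell. Neither list passed against the other chosen genes by camera (adjusted p = 0.335 and 0.901). Of 9 erythropoietin and KIT signalling genes 6 fell, among them JAK2 (-1.31 ± 0.19) and EPOR (-1.26 ± 0.28). Of 12 erythroid transcription factors and cofactors 8 fell and 2 rose. MYB, a factor of immature blood cells, fell by 0.93 ± 0.15, ZFPM1, the partner of GATA1, by 0.91 ± 0.13, LMO2, of the GATA1 complex, by 0.86 ± 0.16 and GATA1 by 0.59 ± 0.18. The call of GATA1 was lost under total count (-0.43), RLE (-0.39) and TMM (-0.39) scaling, without day 0 replicate 1 (-0.62) or 2 (-0.53) and without day 12 replicate 1 (-0.50). MAFG, the partner of NFE2, rose by 0.56 ± 0.069 and ZBTB7A by 0.58 ± 0.083, and KLF1 had -0.23 ± 0.11 and did not pass (adjusted p = 0.126), though limma-trend called it lower (-0.49). The survival genes MCL1 (-1.11 ± 0.17) and BIRC6 (-1.01 ± 0.086) fell, and the third member, BCL2A1, had 0.03 ± 0.061. MYC fell by 1.10 ± 0.15 as 1 of 4 G1/S genes, and CDK6, a kinase of the G1/S transition, had 0.08 ± 0.087. BCL2A1 and CDK6 were called higher under total count (0.20 and 0.25), RLE (0.24 and 0.29) and TMM (0.23 and 0.28) scaling. VHL, which marks hypoxia factors for degradation, fell by 0.64 ± 0.17, a call lost under RLE (-0.44) and TMM (-0.45) scaling. The list of tumour suppressors and cell cycle inhibitors split. Of its 9 genes 4 were lower, among them RB1 (-0.59 ± 0.079) and PPM1D, a phosphatase of the DNA damage response (-0.67 ± 0.095). Another 3 were higher, among them the histone demethylase KDM6A (0.53 ± 0.099) and CDK8. Membership of this fixed list does not make PPM1D or CDK8 a tumour suppressor. CDK8, the Mediator kinase, rose by 0.55 ± 0.073 while MED23 (-0.88 ± 0.082), MED20 (-0.85 ± 0.12) and MED16 (-0.58 ± 0.11), of its head and tail modules, fell.

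Many members of lists of general cell functions fell with scaling to the non-targeting guides, where 490 of all 1223 genes were lower. RLE scaling moved the medians from -0.38 to -0.17 for the mitotic spindle and from -0.34 to -0.14 for Fanconi anaemia genes. It moved them from -0.35 to -0.15 for cholesterol synthesis and from -0.26 to -0.06 for mTORC1 and amino acid sensing. The counts that follow are those with scaling to the non-targeting guides. All 7 mitotic spindle genes, all 5 proteasome genes and all 4 Fanconi anaemia genes fell, with 8 of 12 genes of complexes III to V (10 adjusted over the list alone), 5 of 9 of cholesterol synthesis, 4 of 6 of red cell glycolysis and redox (5), 3 of 5 of the spliceosome (4), 3 of 4 translation factors, 2 of 3 of DNA replication (3), 3 of 4 congenital dyserythropoietic and 2 of 4 Diamond-Blackfan anaemia genes. Of 5 red cell membrane genes 3 fell, among them SLC4A1 and BSG (-0.25 ± 0.078). The call of BSG was lost under total count (-0.09), RLE (-0.05) and TMM (-0.05) scaling and without day 0 replicate 1 or 2 (-0.23 each). Of 9 mTORC1 and amino acid sensing genes 3 fell, LAMTOR4 first (-0.54 ± 0.094), and 7 with the block. Of 82 microRNA genes 9 fell (8 over the list alone, 17 with the block), and of 3 olfactory receptors 0 passed. Apart from BBC3, the apoptosis effectors had -0.14 ± 0.076 for BID and -0.19 ± 0.095 for TNFRSF10B, both lower with the block and without day 12 replicate 1 (-0.22 and -0.29). Apart from the 5 lists that fell and SAGA, no list passed camera (adjusted p from 0.0576 to 0.901). For the apoptosis effectors (median -0.14, mean 0.26), the microRNA genes (median -0.09, mean -0.21), the tumour suppressors (median -0.10, mean -0.14) and the G1/S genes (median 0.01, mean -0.25) camera's direction was up, and the medians of the first 3 turned positive under TMM, RLE and total count scaling. Without day 12 replicate 1 the medians were -0.22 for the apoptosis effectors, -0.17 for the tumour suppressors and -0.08 for the G1/S genes, which had -0.05 without day 0 replicate 3. The microRNA list was called without day 0 replicate 1 (adjusted p = 0.0418) or 3 (0.0376) and without day 12 replicate 2 (0.0384).

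**Figure D2:**
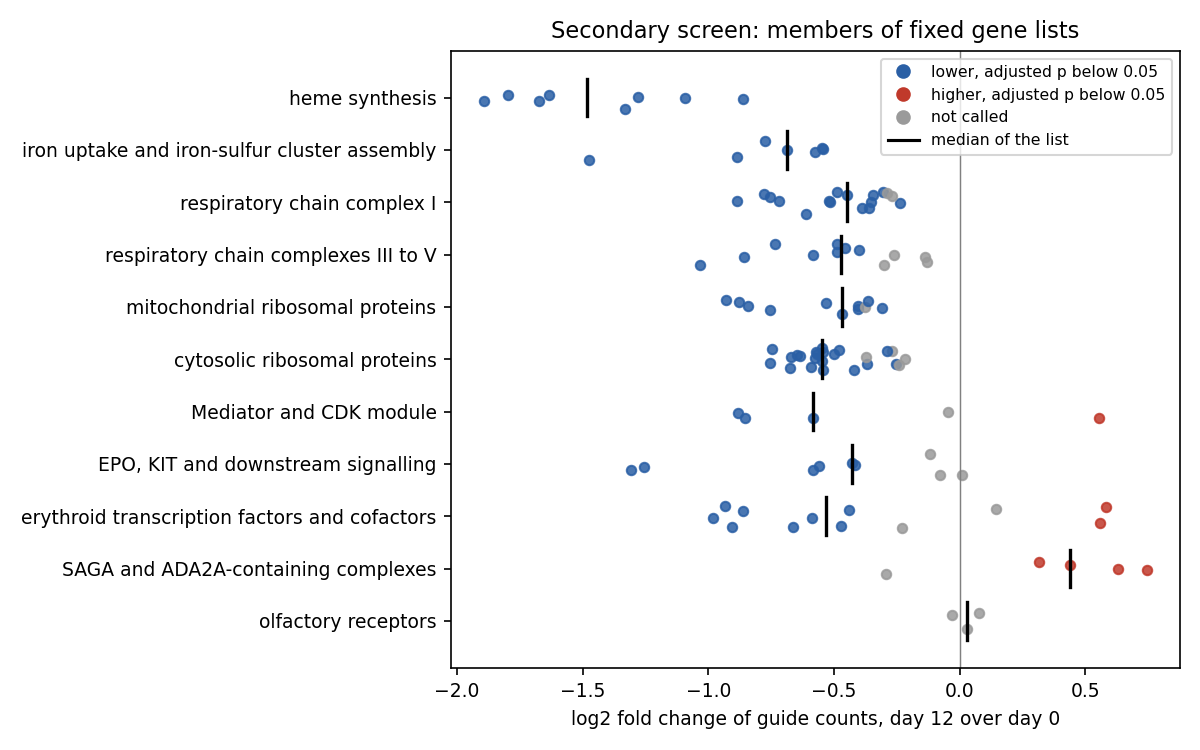
Log2 fold change of summed guide counts, day 12 over day 0, in the secondary screen (horizontal axis) for members of 11 fixed gene lists (vertical axis, with random vertical scatter). Each point is 1 gene, coloured by whether edgeR called it lower or higher at an adjusted p under 0.05, and the black bar is the median of the list, which is -1.48 for heme synthesis and 0.44 for SAGA.

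In total edgeR called 490 genes lower and 38 higher of 1223 in the secondary screen, and of these 54 fell and 6 rose by over 1 log2. Higher genes made up 7.20% of the calls with scaling to the non-targeting guides, 40.3% with TMM, 30.4% with total counts and 42.8% with RLE, since the median of all genes was -0.15, 0.04, 0.01 and 0.05 under these scalings. The 38 genes that rose were called higher under each of them. Genes called lower numbered 329 with TMM, 346 with total counts and 327 with RLE, all of them among the 490. Of the 50 sets of non-targeting guides 0 passed and 2 had an unadjusted p under 0.05. All 9 pairs of libraries had the same sign for 50.2% of genes, against the same 10%, which again leaves out the pairing. Of 12419 single guides 954 fell and 83 rose, and with the block 2603 fell and 194 rose. Without day 0 replicate 1, 2 or 3 the guides that fell numbered 190, 193 and 186 and those that rose 30, 31 and 29. Of the 28 lists 5 fell and 1 rose by camera, fry called 27, and 0 passed with an estimated correlation.

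Ratios of day 0 over plasmid in the secondary screen were, among the named regulators, lowest for EPOR (-1.96), JAK2 (-1.85), MYC (-1.70), GATA1 (-1.67) and MYB (-1.61). The proteasome list had a median of -0.86, as had the spliceosome, and cytosolic ribosomal proteins -0.63, with percentiles of 0.04, 0.03 and 0 among the random lists. Heme synthesis stood at 0.01, percentile 47.8, complex I at -0.24, percentile 1.58, and SAGA at -0.06, percentile 24.8. Of 28 lists 12 were below the 2.5th percentile and 0 above the opposite limit. Non-targeting guides had a median ratio of 0.55.

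Across both screens the same genes moved in the same direction for the most part. ALAS2 had log2 fold changes of -1.31 in the genome-scale and -1.89 in the secondary screen, SRM -1.30 and -1.17, MAPK14 -1.14 (-1.74 without genome-scale day 12 replicate 3) and -1.32, GLRX5 -0.99 and -1.47, FRYL, a large scaffold protein, -1.19 and -1.01, the arginine transporter SLC7A1 -1.10 and -0.94 and F8A1, which has near-identical copies, -0.91 (-1.41 without genome-scale day 12 replicate 2) and -1.11. COL4A3BP had 1.04 and 1.71, and CCZ1 1.02 and 1.01. Of 487 genes that fell in the secondary screen 439 (90.1%) were below 0 in the genome-scale screen, and of 38 that rose 34 (89.5%) were above 0. Of all 1217 genes measured in both, 926 were below 0 in the genome-scale screen and 291 above 0, so part of the shared falls follows from this lean. For both directions together this was 90.1% (95% exact Clopper-Pearson interval 87.2 to 92.5, with genes taken as independent), and sign and call were associated (Fisher's exact test, two-sided, p = 1.85e-26). Over the 1217 genes Pearson's r was 0.52 and Spearman's rho 0.51 across genes, which are not independent replicates. Genes called in both screens by edgeR without the block numbered 0, since the genome-scale screen had none.

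Of the genes called with the block in the genome-scale screen, 23 were in the secondary library and 21 were called there, 14 lower and 7 higher, all in the same direction (Fisher's exact test, p = 8.60e-06). With the block in both screens 22 were called in both. Of the alpha-RRA calls 35 of 39 were called in the secondary screen and 34 in the same direction (Fisher's exact test, p = 2.88e-08). The exception was SPTSSA, a subunit of the enzyme that starts sphingolipid synthesis, with 1.21 ± 0.32 in the genome-scale (0.74 without day 12 replicate 3) and -0.43 ± 0.080 in the secondary screen. The secondary genes were picked by the study, so these shares are not independent of the genome-scale result.

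**Figure D3:**
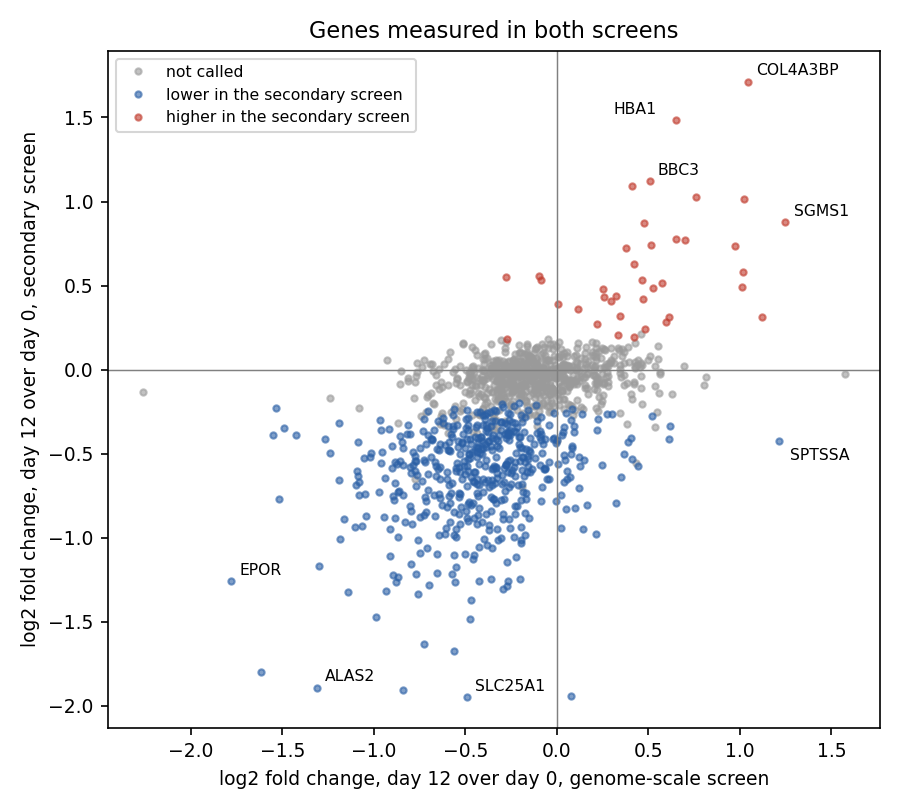
Log2 fold change of summed guide counts, day 12 over day 0, for 1217 genes in the genome-scale screen (horizontal axis) and the secondary screen (vertical axis). Each point is 1 gene, coloured by whether edgeR called it lower or higher in the secondary screen; most called genes lie on the same side of 0 in both screens.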

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

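The tests of the non-targeting excess, of complex I and of multi-copy families were chosen after the results were seen, and the counts over other splits of the samples were planned.

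Non-targeting guides took 4.02% of the reads in genome-scale day 0 replicate 3, above the other 5 cell libraries. These guides target no gene, but sets of them entered the fit of that screen. An expanded subset of cells in that replicate would have carried the excess on to day 12, but the 522 non-targeting guides over 2-fold up against replicates 1 and 2 had a median log2 of 1.84 at day 0 and of -0.0058 at day 12, which argues against it for these guides. The 2587 targeting guides over 2-fold up had medians of 1.31 and 0.74, so an expanded subset is left open for them. Reads of another guide library in this sample may be the source, since 7.14% of 1625 protein kinase guides were over 2-fold up against 1.81% of 2933 zinc finger guides, a ratio of 3.95, while between replicates 1 and 2 neither share was over 3.38%. Of 20 consecutive blocks of 50 non-targeting guides, 11 had 90% or more of their guides elevated and the others 2% or less.

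Complex I fell further in the pair of libraries numbered 3 of the genome-scale screen. A stronger loss of these guides in replicate 3 from an equal start would put them lower at day 12. Their median log2 there against replicates 1 and 2 was -0.053 (quartiles -0.30 to 0.27), which argues against such a loss from an equal start. A stronger loss from a truly higher start is left open. At day 0 the same median was 0.60 (quartiles 0.04 to 1.04), with 36 of 46 genes higher, so excess counts in that day 0 library may account for the larger fall. The fall of the list without that library, and its fall in the secondary screen, are not explained by this excess.

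Guides that fit many genomic sites could lower cell numbers through DNA cutting alone. Of 31 genes of multi-copy families in the secondary screen 5 fell, against 490 of 1223 tested genes, and their median was -0.10, at percentile 81.5 among random lists of secondary genes. The families were picked by gene name, and their guides were not matched to genomic sites. The percentile shows that they fell less than most random lists of these chosen genes. It cannot decide whether cutting at many sites caused falls in that library. An effect of cutting is left open in that library, since 27 of the 31 were below 0, while sets of non-targeting guides had a median of -0.01. The median of all genes there was itself -0.15. In the genome-scale screen 261 genes of such families had a median of 0.0071, at percentile 42.7 of random lists. Of these 124 were below 0 and 137 above, and 0 were called, so the families did not fall against other genes there. A biological difference between these families and other genes was not tested.

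SPTSSA, of sphingolipid synthesis, went opposite ways in the screens in 9 of 9 pairs of libraries each, with log2 fold changes of 1.21 in the genome-scale and -0.43 in the secondary screen. The difference between screens was not tested.

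Of the 10 ways to split the 6 libraries of a screen into 3 and 3, too few exist for a share under 0.05. In the genome-scale screen the real split gave 26 called lists and the highest other 14. It gave 0 genes and 0 guides, as did the highest other. With the real split itself counted, 1 split was as large for lists and 10 were for genes and guides. For the secondary screen the real split gave 528 genes, 1037 guides and 6 lists, and the highest other gave 0, 0 and 1. With the real split itself counted, 1 split was as large for each. Of the splits that part all 3 pairs of numbers, as the real one does, the others gave 14, 5 and 3 lists in the genome-scale and 1, 0 and 0 in the secondary screen, and the splits that part 1 pair gave 2 to 6 and 0 to 1. The split with 14 lists groups day 12 replicate 3 with day 0 replicates 1 and 2.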

How the results depend on the processing

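Fits without the libraries numbered 3, beyond the loss of single libraries, and further scalings for lists were chosen after the data were seen; the other alternatives were planned. Genome-scale genes called numbered 45 lower and 11 higher with DESeq2, 3 lower with limma-trend, 21 and 8 with the replicate block, and 35 and 14 with the guide-level test and alpha-RRA. With the block they were 65 and 29 without both libraries numbered 3 and 69 and 25 without the day 0 library numbered 3, fits with 1 residual degree of freedom that rest on the pooled spread. Leaving out 1 library gave 0 lower and 0 to 1 higher, and other scalings and count minimums gave 0. Genome-scale guides were 53 and 8 with DESeq2 and 14 and 3 with the block. Camera with an estimated correlation called 0 lists and fry 14, and leaving out 1 library gave 19 to 28. Over the alternatives for day 0 over plasmid, 121 list medians in the genome-scale and 82 in the secondary screen stayed within the SD of the day 0 libraries and 58 in each moved further. Most that moved did so under scaling to the non-targeting guides, which shifts all lists alike, or with the median of guides. The median of the apoptosis effectors, 0.12, was reversed to -1.53 when scaled to the median of the non-targeting guides, by the construction of that scaling.

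In the secondary screen alpha-RRA called 140 genes lower. Genes called lower were 346 with total count, 327 with RLE and 329 with TMM scaling. Genes called higher were 151, 245 and 222, because these scalings set the median of all genes near 0. Leaving out 1 library gave 421 to 509 lower and 33 to 46 higher. Guides called lower were 512 with total count scaling, 1749 with DESeq2 and 2603 with the block, and those called higher 133 with DESeq2 and 194 with the block. Leaving out 1 library gave 186 to 1203 lower and 29 to 102 higher. An estimated correlation called 0 lists and fry 27. Genes called in both screens were 35 with alpha-RRA in the genome-scale screen, 22 with the block in both, and 0 to 1 when 1 library was left out. Where no cause is given, the cause was not tested. The block called 591 genes lower and 52 higher in the secondary screen, the 490 and 38 among them. In that screen it changed no other call of a named gene or list beyond those given with the results. In the genome-scale screen the block also called PPM1D lower and PI4KB higher. Genes called in neither setting count as kept even where their sign differed.

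For lists, 377 results in the genome-scale and 275 in the secondary screen kept their direction and their side of the threshold, 20 and 2 fell short of it and 10 and 3 came to pass it. For named genes, 732 and 1150 results were kept, 66 and 16 came to pass the threshold, and 18 in the secondary screen fell short of it. Leaving out genome-scale guides that fit more than 1 gene, and secondary guides shared with the genome-scale library, was not run, since the genome-scale sequences were not used here. At the depth and spread of the genome-scale screen a change of 0.5 log2 was recovered for 1.52% of simulated genes. Most changes of that size were thus not detectable there by the fit without the block. The simulated libraries were not paired, so recovery with the block was not measured.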

Other observations

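The tests on ceramide transport and on RAB7A, and the choice of the tethering complexes, were made after the results were seen.

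The HOPS and CORVET complexes tether endosomes and lysosomes before fusion, and RAB7A acts on the same route. In the secondary screen all 5 measured members fell, VPS11 by 1.05 ± 0.091, VPS18 by 0.79 ± 0.10, VPS16 by 0.77 ± 0.070, VPS8 by 0.62 ± 0.092 and VPS33A by 0.61 ± 0.086, while RAB7A rose by 0.73 ± 0.073 (edgeR, adjusted p of 0.000244 or less for each). In the genome-scale screen 0 of 8 members passed and 5 were below 0, with VPS33A at -0.53 ± 0.19 and VPS41 at +0.44 ± 0.17. Their median was -0.25, at percentile 0.19 of random lists, but the set was picked after its values were seen, so this percentile is not a test.

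COL4A3BP and SGMS1, which act in turn on ceramide, rose, and a rise of the whole pathway of sphingomyelin synthesis might lie behind their values. The 11 members not seen before had a genome-scale median of 0.11, at percentile 89.4 of random lists, which decides nothing. Of these DEGS1 (-0.80 ± 0.23) and KDSR (-0.69 ± 0.21) were the 2 below 0, and SPTLC1 had +0.62 ± 0.40. In the secondary screen 3 of 5 such members fell, DEGS1 (-0.58 ± 0.084), KDSR (-0.42 ± 0.078) and, against its genome-scale sign, SPTLC1 (-0.34 ± 0.10), all earlier steps of the pathway. The call of SPTLC1 was lost under total count (-0.17), RLE (-0.13) and TMM (-0.14) scaling and without day 0 replicate 1 (-0.33) or 2 (-0.32). Of the 5 members seen before, 4 rose in the secondary screen and SPTSSA fell (-0.43 ± 0.080), against its genome-scale value of 1.21 ± 0.32. The falls in the secondary screen argue against a rise shared by all members, and a rise of part of the pathway is left open.

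A rise of the whole RAB7A route might likewise lie behind the values of RAB7A, CCZ1 and C18orf8. The 9 members not seen before had a genome-scale median of 0.03, at percentile 47.3 of random lists. Of these 4 were below 0 and 5 above, from -0.67 ± 0.19 for VPS29 to +0.49 ± 0.19 for PLEKHM1. The 5 members seen before, RAB7A among them, were all above 0, with a median of 0.98. The values argue against a rise shared by the 9, and a rise of part of the route is left open.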
